A study of Mus musculus with 8 samples.

How the data were processed

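Aortic root and ascending aorta from 16-week-old control mice and mice with a heterozygous Fbn1 mutation (a model of Marfan syndrome) were pooled by genotype and sex by the authors. The pools were digested with liberase and elastase and sorted into cells traced by Nkx2-5-Cre and tdTomato, which mark the second heart field (SHF), and untraced cells (nonSHF). Each fraction gave 1 single-cell library with 10x Chromium 3′ version 3 chemistry, so 4 pools gave 8 libraries in 4 groups of 2. Replicate 1 of each group is the female pool and replicate 2 the male pool, so sex and replicate cannot be separated. Per the labels' protocols both fractions of a pool come from the same suspension, so they were treated as a pair. The female minus male differences of the fractions correlated at r = 0.466 in control and 0.520 in Marfan pools over 7912 genes.

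The authors processed the reads with Cell Ranger and Seurat on build mm10; versions and settings are not given in the sources used here. The deposited values are natural logarithms (unit ln) of 1 plus a count, in 18188 genes and 39031 cells. After the log was undone, 0 of 94650854 nonzero values were off a whole number by more than 1e-06. These whole numbers summed to between 6055 and 9157 in every cell, a narrow range that raw counts do not have. They were therefore read as counts evened for depth by the authors. The step that evened them is not named in the sources used here, and the raw depth per cell is unknown. The total of evened counts per library lay between 21196671 and 43701109, and the median number of genes per cell between 1506 and 2791. Intervals for shares of cells cover counting error only.

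Cells from all libraries were clustered together on 2000 variable genes, 30 principal components and 20 neighbours with Leiden at resolution 0.8 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). No batch correction was applied. Doublets were called with Scrublet at an expected rate of 0.06 and removed: 537 cells. In 3 libraries Scrublet called only 4, 5 and 6 cells, so doublets there stay largely uncalled. A minimum of 500 genes and a maximum of 10% mitochondrial counts removed 0 cells. Clusters were named from fixed marker lists, with at least 3 markers detected in 25% of the cluster's cells and a marker among its 10 leading genes. The list with most markers among the leading genes gave the name. A modulated smooth muscle name also required Myh11, Acta2, Tagln and Cnn1 to be widely detected in the cluster. Clusters with at least 25% doublet calls, or with more leading markers of another class, stayed unnamed. Names end in "-like", since no other evidence of cell type was used. The smooth muscle class joined the smooth-muscle-like clusters and the modulated smooth-muscle-like cluster, which led with markers of modulated smooth muscle (cells that keep contractile genes and gain matrix and adhesion genes). Of 22 clusters, 4 with 8243 cells stayed unnamed and entered no class. The largest of these held the fibroblast markers Dpt and Dcn, so the fibroblast class may not cover all fibroblasts. Another, of 1681 cells, was led by genes that include Chad, Comp and Penk, of the valve interstitial list. Its leading genes also include Spp1, Cytl1 and Tnfrsf11b, of the modulated smooth muscle list.

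The evened counts of each class were summed per library and expressed per 10000 evened counts of that sum, called the level. Libraries with under 20 cells of a class were left out of that class. Genes with a level of at least 0.1 in at least 2 libraries were fitted with limma 3.58.1 (R 4.3.3) on the log2 of the level plus 0.1, with a trend of variance on mean level. Marfan against control within a lineage was fitted with group and sex and without the pool. Where both fractions of a pool entered, they thus counted as independent. Since the fractions of a pool were correlated, the spread between pools may be underestimated and these p values too small. SHF against nonSHF, and the difference of the Marfan effects between lineages (interaction), were fitted with the pool as a block. All libraries shared 1 estimate of spread. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The plan named tests for raw counts. They were not run, because the values are not raw counts, and limma took their place after the unit was known. Changes are given as log2 ± SE, levels as mean ± SD with n = 2 libraries unless stated. Where the median change of all genes exceeded 0.1, changes of some genes are also given relative to that median.

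Choices made before the data were examined were the groups, the comparisons, the alternatives, the marker lists, the gene lists and the rule for naming genes. The rule takes 9 genes always named for smooth muscle genotype comparisons, the 8 highest and 8 lowest changes past the threshold with a mean level of at least 0.2 and the same sign in both sexes, and up to 3 members per list with the smallest p. Where fewer than 5 genes passed, it takes the 5 with the smallest p, and some of these are left out for length. Some genes that the rule takes are not reported here. Predicted, ribosomal and sex-linked genes are counted but not named under the highest and lowest changes. Fixed lists of genes were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Their p values were adjusted over the lists of 1 comparison. The calls of camera at the preset correlation were lost with an estimated correlation in all 13 comparisons, where the lowest adjusted p was 0.154. On simulated data camera at an estimated correlation missed a list changed 1.5-fold in most comparisons (in macrophages adjusted p = 0.943 and 0.991). It called that list only between genotypes in smooth muscle (adjusted p from 0.0140 to 0.0219), while the preset correlation called it in each. The simulated genes varied independently of each other, so the simulation cannot show which correlation is right for the real lists. The loss with an estimated correlation therefore does not decide whether a list changed, and neither do the calls at the preset one. Gene positions come from GENCODE vM21 on mm10.

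To compare list shares per cell, smooth muscle cells were thinned to 6600 evened counts, and cells with fewer were left out, mainly in the male control nonSHF library, where 1747 of 2204 cells were kept. A threshold for a high modulation share was set at the 95th percentile of all control cells of the class. Shares of cells were not tested, since 2 libraries against 2 allow no exact two-sided p below 0.333. The fit was tested on simulated data with known changes, using either a spread smoothed over genes or each gene's own residual spread. Changes were set only in genes with a mean log2 level above the median, and genes varied independently of each other. The recovery rates thus do not cover genes at lower levels.

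Alternatives set beforehand were no gene filter, doublet calls kept, Leiden at 1.6, equal cells and totals per library, no sex term, no pool block, only the libraries of the 2 groups compared, smooth-muscle-like clusters only, and each library or pool left out. Alternatives chosen after seeing the data were pseudocounts of 0.02 and 0.5, median-of-ratios scaling of the levels, cells with 1500 to 2300 genes (matched cells), as many random cells, both control nonSHF libraries left out, fibroblasts without the cluster led by Igfbp6, and macrophages without cells holding S100a8 or S100a9. The window does not even out genes per cell in full: within it the medians in control and Marfan nonSHF (female and male) were 1931 and 1641.5 against 2032 and 2102.5 in smooth muscle, 1760 and 1567 against 1922 and 1911 in fibroblasts, and 1836.5 and 1632 against 1942.5 and 2017.5 in macrophages. Further ones were the macrophage fit with group only when a library was left out, and list shares in smooth-muscle-like clusters only. Dendritic, lymphatic endothelial, Schwann, pericyte and mesothelial cells were counted but not tested between groups.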

Results

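The data are single-cell RNA profiles of the aortic root and ascending aorta of 16-week-old control mice and mice with a heterozygous Fbn1 mutation (Marfan mice). Fbn1 encodes fibrillin-1, the main protein of microfibrils. Cells of the second heart field (SHF) lineage and untraced cells (nonSHF) were sorted from the same suspensions, so that Marfan and control cells could be compared within each embryonic origin. The 8 libraries form 4 groups of 2, with 1 female and 1 male pool in each. Control nonSHF libraries held 5265 and 3113 cells, control SHF 5616 and 4840, Marfan nonSHF 5022 and 4581, and Marfan SHF 5177 and 5417 (female and male). The totals of evened counts lay between 21196671 and 43701109 per library. The median number of genes per cell was 2062 and 1506 in control nonSHF, 2578 and 2440.5 in control SHF, 2666.5 and 2688 in Marfan nonSHF, and 2791 and 2479 in Marfan SHF. The control nonSHF libraries thus held the fewest genes per cell, and every comparison against them carries this difference in genes per cell.

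The sex labels matched the transcripts. Female libraries held Xist, the transcript of the inactive X chromosome, at levels from 7.08 to 9.76 per 10000 evened counts, and male libraries held the Y-linked Ddx3y at levels of at least 0.940. Xist stood at 0.869 in the male control nonSHF library and at no more than 0.0721 in the other male libraries. In that library 58.4% of cells held exactly 1 Xist count and 3 cells held more.

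Smooth-muscle-like cells made up a smaller share of the untraced cells in Marfan mice, and fibroblast-like and macrophage-like cells a larger share. The smooth muscle class, the modulated cluster included, held 71.5% ± 0.890 of cells in control nonSHF and 46.4% ± 1.33 in Marfan nonSHF (SD, n = 2 in each group here and below). In SHF cells it held 44.7% ± 7.37 and 33.6% ± 7.32. Fibroblast-like cells, which lie mainly in the adventitia, made up 9.58% and 4.83% of the female and male control nonSHF libraries and 17.5% ± 0.230 of Marfan nonSHF cells, against 29.0% ± 4.52 and 34.5% ± 8.72 in SHF. Macrophage-like cells made up 7.61% ± 2.57 and 14.2% ± 0.915 of nonSHF cells. In the SHF fraction they were nearly absent, at 0.114% ± 0.135 and 0.145% ± 0.0457. Endothelial-like cells held 0.427% ± 0.149 of control nonSHF, 1.75% ± 0.617 of Marfan nonSHF, 0.811% ± 0.246 of control SHF and 1.88% ± 1.02 of Marfan SHF cells. A modulated smooth-muscle-like cluster of 449 cells, led by Fn1, Nrgn, Igfbp2, Mgp and Tnfrsf11b, held 0.166% ± 0.0072 of control nonSHF and 3.13% ± 1.51 of Marfan nonSHF cells, and 0.242% ± 0.162 and 1.11% ± 0.235 in SHF. The nonSHF differences between genotypes in smooth muscle, fibroblast and macrophage shares were larger than the spread between replicates. The smooth muscle and fibroblast differences in SHF were not clearly larger than that spread. These shares were not tested, since 2 libraries against 2 allow no exact two-sided p below 0.333.

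**Figure D1:**
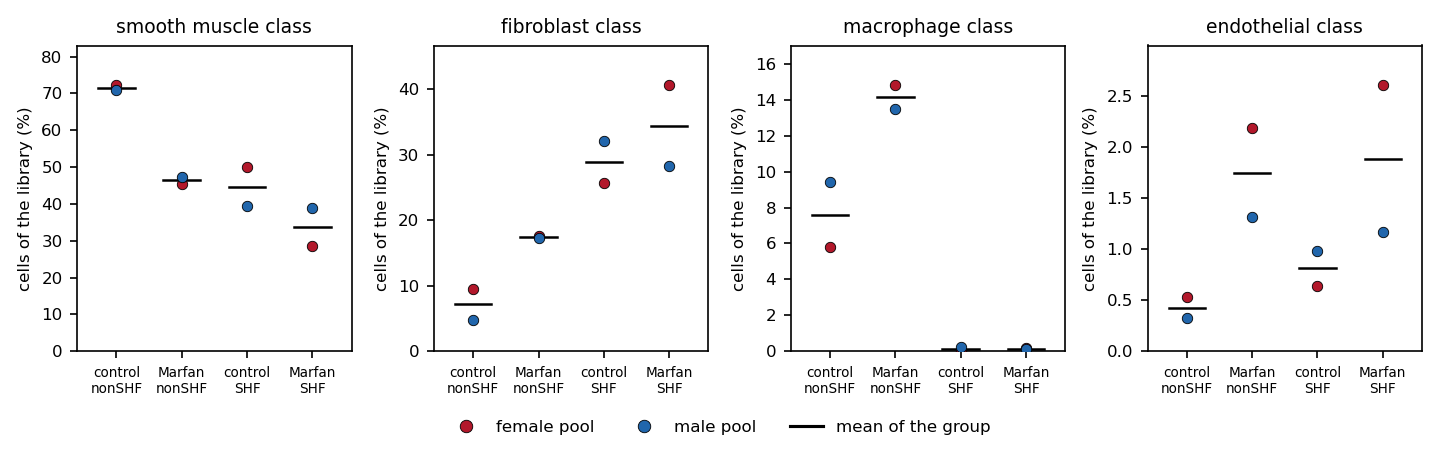
Share of cells per library (percent of the library's cells, linear axis from 0) in the smooth muscle, fibroblast, macrophage and endothelial classes, with 1 point per library and the female and male pools marked. Macrophage-like cells lie near 0 in the 4 SHF libraries and average 7.61% in control nonSHF and 14.2% in Marfan nonSHF.

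The comparison of Marfan with control within the SHF lineage asks how traced smooth muscle differs with genotype. In Marfan SHF smooth muscle 55 genes rose, 8 of 22 measured modulation genes among them, and 32 fell. The class drew on different clusters here too: 3 smooth-muscle-like clusters held 12.6% ± 4.39, 4.86% ± 0.9498 and 3.57% ± 0.816 of control SHF cells and 3.78% ± 0.350, 1.38% ± 1.25 and 8.22% ± 2.59 of Marfan SHF cells. Igfbp2 and Sncg lead the last of these, and whether they changed within clusters was not tested. The largest rise was in Igfbp2 (chromosome 1, 72824503 to 72852474), a binding protein of insulin-like growth factors, by 1.77 ± 0.18 from a level of 0.634 ± 0.229 in control to 2.45 in Marfan cells (adjusted p = 0.00132). Vcam1, an adhesion receptor for leukocytes, rose by 1.23 ± 0.15 from 0.596 ± 0.0983 to 1.52 ± 0.103, and Sncg, which encodes gamma-synuclein, by 1.17 ± 0.15. Fn1, the gene of fibronectin, rose by 0.97 ± 0.12, Fxyd5, a regulator of the sodium pump, by 0.98, Nrgn, which encodes a calmodulin-binding protein, by 0.97, and Fst, the activin antagonist follistatin, by 0.92. Mmp3, a matrix metalloproteinase, rose by 0.91, Col8a1, a short-chain collagen, by 0.83, and Thbs1, which can activate latent TGF-beta, by 0.80. Aggrecan (Acan) and matrix Gla protein (Mgp), an inhibitor of calcification, each rose by 0.72, and Fbln2 (fibulin-2) rose by 0.66. Among genes that fell, Kcnj15, an inward rectifier potassium channel, changed by -1.16 ± 0.09, and Wif1, a secreted Wnt inhibitor, by -1.12 ± 0.08 (adjusted p = 0.000428 for both). Fibin changed by -0.98, the desmosome gene Dsp by -0.89, the serine protease gene Htra3 by -0.82, Brip1, a DNA helicase, by -0.79, and Filip1l, a binder of filamin, by -0.73. Mfap5 and Mfap4, which encode proteins bound to microfibrils, changed by -0.73 and -0.69. Without Marfan SHF replicate 1 none of these genes passed.

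Fbn1 itself (chromosome 2, 125300594 to 125507993) did not pass the test in SHF smooth muscle, at 0.02 ± 0.10 and -0.02 under median-of-ratios scaling. Acta2, Tagln and Myh11, the core contractile genes, stood at -0.06, 0.02 (-0.02 under that scaling) and -0.36 (adjusted p = 0.173), none past the threshold. Klf4, a factor of smooth muscle dedifferentiation, stood at 0.18, Tnfrsf11b, the decoy receptor osteoprotegerin, at 0.50, and Col1a1 at 0.21, none past the threshold.

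By fixed lists, 8 of 22 measured modulation genes rose in SHF smooth muscle and 0 fell, with 13 higher and 2 lower adjusted over the list alone. Igfbp2, Vcam1 and Fn1 led them (camera in limma, adjusted p = 1.34e-08, and adjusted p = 0.260 with an estimated correlation). Of 24 contractile genes 1 fell, Synpo2, an actin-bundling gene of the Z disc, by 0.52, with 0 higher and 4 lower adjusted over the list alone. The list lay lower by camera (adjusted p = 1.34e-08, and adjusted p = 0.260 with an estimated correlation), and under median-of-ratios scaling Synpo2 had an adjusted p of 0.0664. Of 17 elastic fibre genes 1 rose, Fbln2, and 2 fell, Mfap5 and Mfap4 (2 and 2 adjusted over the list alone), with a median of 0.05 and a mean of -0.01, so that these differ in sign. Of 15 genes of proteases and their inhibitors 2 rose, Mmp3 and Plat, the tissue plasminogen activator, by 0.91 and 0.45, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00712, and adjusted p = 0.409 with an estimated correlation). Of 13 proteoglycan and cartilage genes Acan and Mgp rose and Ogn, a small leucine-rich proteoglycan, fell by 0.52 (adjusted p = 0.0831 under median-of-ratios scaling), with 6 higher and 5 lower adjusted over the list alone. Of 15 collagens Col8a1 rose (2 and 0 adjusted over the list alone), and of 19 TGF-beta genes Thbs1 rose (2 and 0). Of 8 inflammation genes Vcam1 rose (2 and 0), and of 11 genes of endothelial activation and flow Vcam1 and Fn1 rose (3 and 1). In 15 other lists with 142 measured genes limma called 0 genes, and 30 had an unadjusted p under 0.05. These lists hold interferon, mitochondrial respiration, mitochondrially encoded, unfolded protein response, Notch, vasoactive receptor, integrin, second heart field, neural crest, Hox, dissociation, fibroblast subtype, resident macrophage, inflammatory macrophage and antigen presentation genes.

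In all, 87 of 8208 genes differed between Marfan and control SHF smooth muscle, 55 higher and 32 lower (46 and 42 with median-of-ratios scaling), and 915 had an unadjusted p under 0.05. The changes had the same sign in both sexes in 87 of 87. The count rests on few libraries: it was 0 by limma without Marfan SHF replicate 1 (406 genes at an unadjusted p under 0.05), 3 without Marfan SHF replicate 2, 27 without control SHF replicate 1 and 19 without control SHF replicate 2. It was 6 with no sex term, 6 with no gene filter, and 391 with only the libraries of the 2 groups. In cells matched to 1500 to 2300 genes, an alternative chosen after seeing the data, 9 genes passed. Among them were Igfbp2 (1.56), Thbs1 (1.96), Wif1 (-1.49), Sncg (1.22) and Fst (1.22). All 80 called genes that could be tested kept their sign, but matched cells are a part of the same cells, which by itself favours this. Kcnj15 (-0.68, adjusted p = 0.498), Mmp3 (0.61, adjusted p = 0.996), Nrgn (0.82, adjusted p = 0.437), Fn1 (1.04, adjusted p = 0.1005) and Vcam1 (1.37, adjusted p = 0.0551) did not pass there. Nor did Col8a1, Acan, Mgp, Fbln2, Plat, Dsp, Htra3, Brip1, Filip1l, Mfap5, Mfap4, Synpo2 and Ogn. Of these Col8a1 stood at 0.90, Fbln2 at 0.72, Dsp at -1.01, Htra3 at -0.82, Brip1 at -0.70, Filip1l at -0.67 and Mfap5 at -0.64 in matched cells.

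In untraced smooth muscle the same comparison came with a shift of the whole transcriptome. The median change of all genes was 0.29, and relative to it each change is lower by that amount, as given for the leading genes. Igfbp2 rose by 2.53 ± 0.18 (relative 2.24), from a level of 0.453 ± 0.106 to 3.44 ± 2.26, and Cytl1, a secreted protein of cartilage, by 1.90 ± 0.17 (relative 1.61). Sncg rose by 1.80 (relative 1.51), Spp1, which encodes osteopontin, by 1.65 (relative 1.37, and 0.34 with an adjusted p of 0.446 in as many random cells as were matched), and the metalloproteinase inhibitor Timp1 by 1.57 (relative 1.29). Vcam1 rose by 1.41 (relative 1.12), Tnfrsf11b by 1.34 (relative 1.06) and galectin-3 (Lgals3) by 1.33 (relative 1.05). Kcnj15 changed by -1.64 ± 0.09 (relative -1.92). The copper chaperone Cox17, the ATP synthase gene Usmg5 and the peptide amidating enzyme Pam each changed by -1.26, Sec61g of the translocon by -1.23 and the splicing gene Snrpg by -1.21. The microfibril genes Mfap5 and Mfap4 changed by -1.15 and -0.90, Fbln1 (fibulin-1) by -1.36, the proteoglycan gene Prelp by -1.15, and the fibrillar collagens Col1a1 and Col3a1 by -0.68 and -0.67. In matched cells the median change of all genes was 0.02, though genes per cell still differed there, with medians of 1931 and 1641.5 in control and 2032 and 2102.5 in Marfan nonSHF. Among these cells Igfbp2 (1.38), Cytl1 (2.32), Sncg (1.86), Tnfrsf11b (0.93), Lgals3 (1.14), Kcnj15 (-1.77), Mfap5 (-1.20) and Mfap4 (-0.98) passed the test again. Col1a1 (-0.61), Col3a1 (-0.63) and Fbln1 (-0.34) did not, nor did Myh11, Tnc, Tpm1 and Cox6c.

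Fbn1 stood at 0.00 ± 0.10 (relative -0.28) in untraced smooth muscle, and at -0.38 under median-of-ratios scaling, where it passed the test (adjusted p = 0.0207). Acta2 and Tagln stood at 0.33 and 0.27, neither past the threshold, and at -0.09 and -0.14 under that scaling. Klf4 stood at 0.31, and at -0.09 under it. Myh11, the smooth muscle myosin heavy chain, changed by -0.41 (relative -0.70, adjusted p = 0.00551), a call lost without Marfan nonSHF replicate 2 (-0.30). Without control nonSHF replicate 1 Acta2 (0.58) and Tagln (0.53) passed, and without control nonSHF replicate 2 Klf4 (0.88) did.

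Of 22 modulation genes 13 rose and 3 fell in untraced smooth muscle (13 and 3 adjusted over the list alone), with Igfbp2, Lgals3 and the matrix glycoprotein gene Tnc (0.83) in front. Camera did not set them apart from other genes (adjusted p = 0.694, and adjusted p = 0.808 with an estimated correlation). Of 24 contractile genes 3 rose and 8 fell, among them Flna (filamin A) by 0.66, Tpm1 (tropomyosin) by 0.62 and Synpo2 by 0.57, with 2 higher and 8 lower adjusted over the list alone (camera adjusted p = 4.15e-06, and adjusted p = 0.381 with an estimated correlation). Of 15 collagens 2 rose and 6 fell (2 and 6 adjusted over the list alone). Of 17 elastic fibre genes 6 rose and 4 fell (6 and 4), with a median of 0.16 and a mean of -0.04, so that these differ in sign, and lay lower by camera (adjusted p = 0.0131, and adjusted p = 0.437 with an estimated correlation). Of 18 genes of mitochondrial respiration 6 rose and 8 fell (6 and 8), with Cox6c changed by -0.91. All 6 measured inflammatory macrophage genes rose (6 and 0), among them the chemokines Ccl2 by 0.91 and Ccl4 by 0.62, and so did 6 of 8 inflammation genes (6 and 0). Macrophage-like cells were present in these libraries, and 10 macrophage genes stood in smooth muscle at a median of 0.0424% and 0.0777% of their macrophage level in control nonSHF and of 0.136% and 0.0881% in Marfan nonSHF (female and male), so that this value was higher in Marfan libraries of both sexes. These 10 genes include Ccl2, Ccl3, Ccl4 and Cxcl2 of the inflammatory macrophage list, so a rise within smooth muscle would raise this value too. It therefore cannot tell macrophage RNA from such a rise. Of 13 proteoglycan and cartilage genes 4 rose and 5 fell (4 and 5), of 15 protease genes 7 and 3 (7 and 3), and of 19 TGF-beta genes 4 and 1 (3 and 0). The proteoglycan list had a median of -0.01 and a mean of 0.07. The medians of the protease and TGF-beta lists, 0.22 and 0.16, lay above 0 but below the median of all genes, and camera, which sets a list against the other genes, gave them a lower direction (adjusted p = 0.591 and 0.208). The cell cycle list was measured too thinly to test.

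Of 8208 genes 5588 passed the test, 4963 higher and 625 lower. The class drew on different clusters in the groups compared: a smooth-muscle-like cluster with a median of 1788 genes per cell held 40.2% ± 6.26 of control and 2.41% ± 0.630 of Marfan nonSHF cells, and another, with a median of 2683, held 3.11% ± 3.21 and 15.2% ± 5.25. No alternative held the clusters fixed. With median-of-ratios scaling 1874 were higher and 1995 lower. In matched cells 226 passed, 113 in each direction, and 219 of them were calls of all cells. Of 4933 calls of all cells that could be tested there, 3909 kept their sign, which the cells shared by both sets favour by themselves. As many random cells gave 3797. Of the 55 genes that rose in SHF smooth muscle 54 also rose in nonSHF (33.3 expected if independent), and of the 32 that fell 24 also fell (2.44 expected). Against calls of matched nonSHF cells the overlaps were 23 of 49 (0.746 expected) and 13 of 31 (0.476 expected). Both comparisons use fractions of the same 4 pools and so are not independent, which leaves open how far the overlaps exceed what the shared animals bring.

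**Figure D2:**
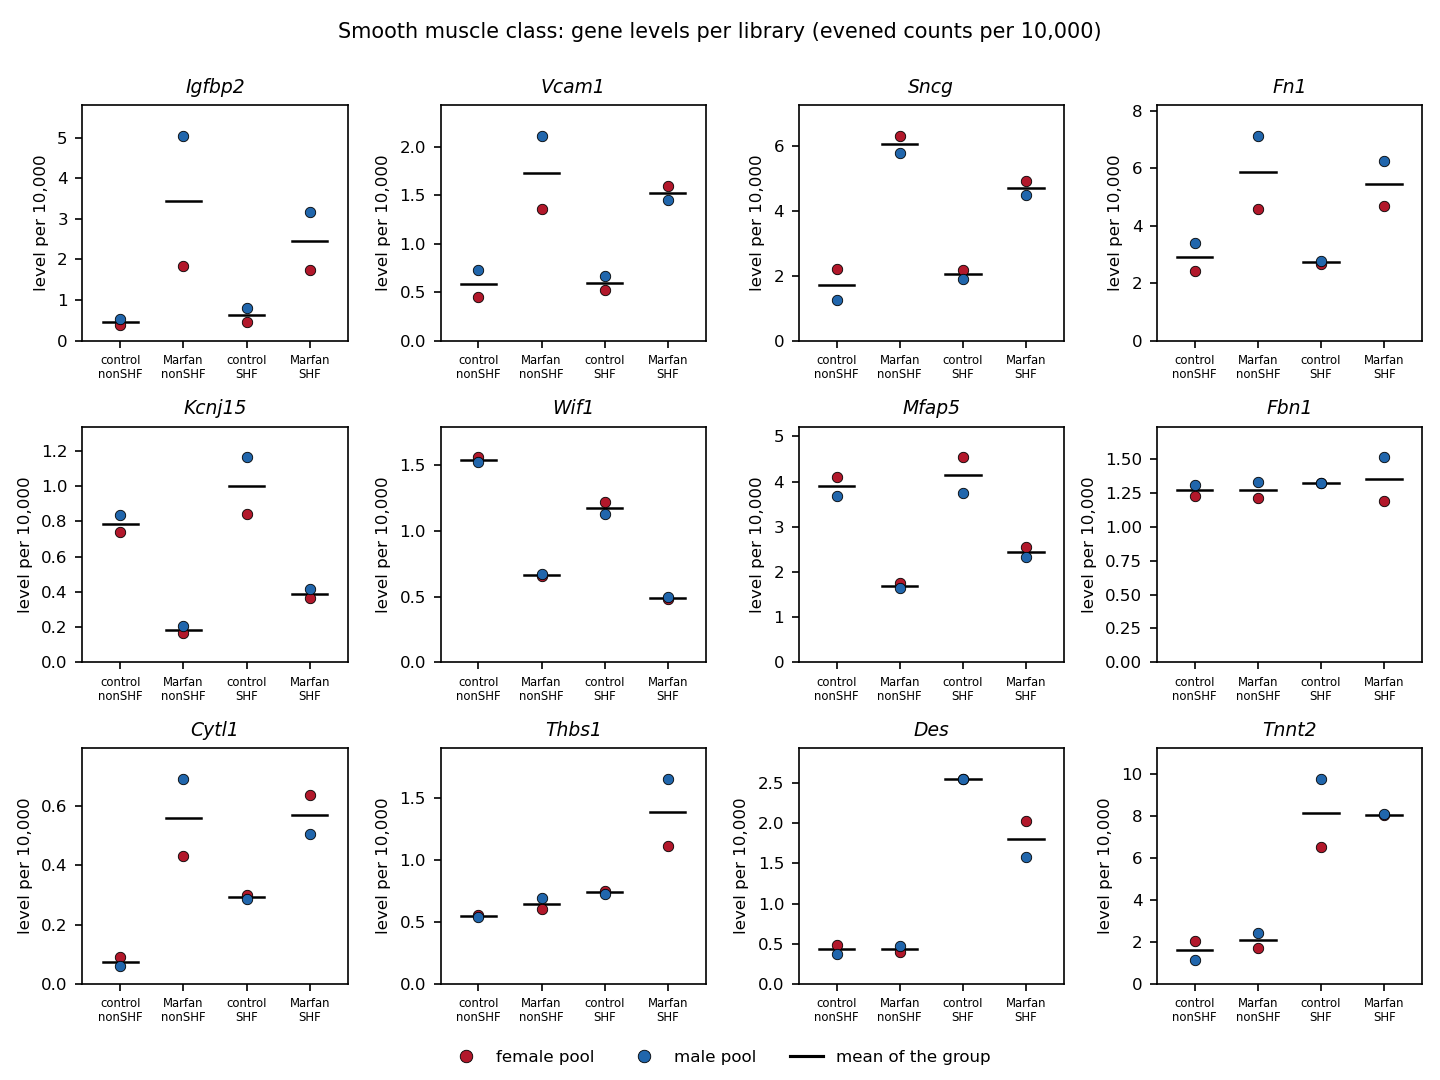
Level per 10000 evened counts (linear axes from 0) of 12 genes in the smooth muscle class of each library, with 1 point per library, female pools in red, male pools in blue and a line at each group's mean. Igfbp2 averages 0.634 in control SHF and 2.45 in Marfan SHF, and 0.453 and 3.44 in nonSHF, while Fbn1 stays between 1.27 and 1.35, with a change of -0.38 in nonSHF under median-of-ratios scaling.

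The interaction asks whether the Marfan effect differs between SHF and nonSHF smooth muscle. The change of Cytl1 was smaller in SHF by -1.13 ± 0.22, that of Spp1 by -1.10 ± 0.14 (0.84, of the other sign, in as many random cells, and not measured in matched cells), that of the stress-response factor Atf5 by -0.98 and that of Tnfrsf11b by -0.85. The change of Pam was higher in SHF by 1.10, that of Tmsb10, which encodes an actin-sequestering thymosin, by 1.07, that of Col1a1 by 0.90 and that of Thbs1 by 0.59. For Vcam1 the difference was -0.18 ± 0.21 (0.15 under median-of-ratios scaling) and did not pass, so no difference between lineages was detected. The median of all genes was -0.26, and relative to it Cytl1 stood at -0.88, Spp1 at -0.85, Thbs1 at 0.85 and Col1a1 at 1.16. In matched cells 10 genes passed, among them Cytl1 (-2.60), Thbs1 (1.62) and Col1a1 (1.13). Pam (1.07, adjusted p = 0.0718), Tmsb10 (0.86, adjusted p = 0.221), Tnfrsf11b (-0.87, adjusted p = 0.291) and Atf5 (-0.92, adjusted p = 0.247) did not, and of the 8 highest and the 8 lowest genes 2 and 1 did. Under median-of-ratios scaling Tnfrsf11b and Atf5 did not pass (adjusted p = 0.0706 and 0.0732), and without Marfan replicate 2 none of the named genes did (adjusted p from 0.224 to 0.253).

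Of 22 modulation genes 4 had a higher and 7 a lower Marfan effect in SHF (4 and 7 adjusted over the list alone). Their median was -0.17, while camera, set against the other genes, gave a higher direction (adjusted p = 0.0949). Of 15 collagens 3 had a higher one (3 and 0; camera adjusted p = 9.87e-10, and adjusted p = 0.465 with an estimated correlation), and of 6 inflammatory macrophage genes 4 a lower one (0 and 5 adjusted over the list alone). In all 2774 of 8208 genes passed, 217 higher and 2557 lower, and with median-of-ratios scaling 468 higher and 124 lower. The count was 0 by limma without Marfan replicate 2 (1620 genes at an unadjusted p under 0.05), 576 without control replicate 2 and 1694 without Marfan replicate 1. It was 0 with no gene filter (5152 genes at an unadjusted p under 0.05).

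SHF and nonSHF smooth muscle differed in some of the same genes in both genotypes, and the class drew on different clusters. A smooth-muscle-like cluster led by genes that include Tnnt2, Pln and Psd held 15.5% ± 1.30 of control SHF and 5.49% ± 2.40 of control nonSHF cells, and 12.5% ± 3.59 and 4.73% ± 0.915 in Marfan mice. Another held 4.86% of control SHF and 40.2% of control nonSHF cells, and changes within clusters were not tested. In control mice Des, which encodes desmin, was higher in SHF cells by 2.34 ± 0.13 (relative 2.12 to a median of 0.22), and in Marfan mice by 1.83 ± 0.13. Tnnt2, a troponin of cardiac muscle, was higher by 2.29 in control (relative 2.08) and 1.93 in Marfan cells. The exchange factor gene Psd was higher by 2.02 and 1.53 (relative 1.80 in control), and the chemokine Cxcl12 by 1.66 and 1.63 (relative 1.44 in control). In control cells Rgs5, a regulator of G protein signalling, was higher by 1.45 (relative 1.24) and phospholamban (Pln) by 1.23 (relative 1.01). Cd34, Arhgdib and Rgs17 were higher by 1.31, 1.32 and 1.23 (relative 1.09, 1.10 and 1.01). In Marfan cells the small proteoglycans Lum and Dcn were higher in SHF by 2.01 and 1.83, Apoe, an apolipoprotein, by 1.34 and Thbs1 by 0.97, while Dcn stood at 1.14 in control cells (relative 0.92). Lum and Dcn are also fibroblast markers, as is Serpinf1, at 1.23 in Marfan cells, a call lost without the pool block (adjusted p = 0.0624) and without either Marfan pool (adjusted p = 0.214 and 0.112). Fibroblast-like cells were more frequent in the SHF libraries, and fibroblast RNA or fibroblasts within the smooth muscle class were not tested for this comparison. Lower in SHF cells of both genotypes were Tes, a focal adhesion gene, by -0.94 and -1.09, Abcc9, a subunit of potassium channels, by -0.84 and -0.85, and Acan, by -0.73 in control cells (relative -0.95) and -0.94 in Marfan cells under median-of-ratios scaling. In control cells Notch2 changed by -0.89, Abhd2 by -1.09 and Napepld by -0.88, and in Marfan cells Spp1 by -1.35 (0.33 in as many random cells, and not measured in matched cells), Timp4 by -0.94 (-0.35 with an adjusted p of 0.697 in matched cells), Egr3 by -0.92, Hacd4 by -0.84 and Fez1 by -0.79. In Marfan cells the calls of Egr3 and Abcc9 were lost without Marfan replicate 1 (adjusted p = 0.0576 for both) and that of Fez1 without Marfan replicate 2 (adjusted p = 0.0623). That of Egr3 was also lost without the pool block (adjusted p = 0.229).

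Of 9 second heart field factors 4 were higher and 1 lower in control SHF smooth muscle (4 and 1 adjusted over the list alone), and 3 were higher in Marfan cells (3 and 0). Tcf21 was higher by 1.13 and 1.07, Isl1 by 0.83 and 0.77, and Gata4 by 0.53 and 0.47, a call lost without control replicate 2 in control (0.38) and without Marfan replicate 1 in Marfan cells (0.33). In control cells 5 of 9 neural crest factors were also higher in SHF, among them Twist1 by 0.76 (5 and 0 adjusted over the list alone), and 2 in Marfan cells (3 and 1). These counts in control cells do not set the lists apart, since 3952 of 8208 genes were higher in all. Camera did not call either list there (adjusted p = 0.7498 and 0.758, second heart field and neural crest), and in matched cells 1 of 8 second heart field and 0 of 9 neural crest factors were higher. Of 6 Hox and positional genes Meis2 was higher by 0.53 and 0.57, with an adjusted p of 0.0630 under median-of-ratios scaling in control cells and calls lost without either Marfan pool in Marfan cells (adjusted p = 0.228 and 0.261). Of 8 vasoactive receptor genes 4 were higher and 1 lower in control SHF cells (4 and 1 adjusted over the list alone). The inflammatory macrophage genes were lower in SHF cells, 3 of 6 in control (0 and 4) and 4 of 6 in Marfan mice (0 and 4; camera adjusted p = 4.48e-11, and adjusted p = 0.307 with an estimated correlation). Among them Cxcl2 changed by -0.98 and -1.60, Ccl4 by -0.67 and -1.25, and Ccl2 by -1.19 in Marfan cells. Macrophage-like cells were nearly absent from the SHF libraries, and whether their RNA accounts for these genes was not tested.

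In control mice 4392 of 8208 genes passed, 3952 higher and 440 lower in SHF, and with median-of-ratios scaling 1055 higher and 1422 lower. In matched cells 408 passed, 126 higher and 282 lower, while Gata4, Twist1 and Meis2 did not, and without control replicate 2 the count was 857. In Marfan mice 232 passed, 118 higher and 114 lower, with 152 higher and 81 lower under median-of-ratios scaling. In matched cells Gata4, Meis2, Timp4 and Egr3 did not pass there. That count was 50 without Marfan replicate 1, 83 without Marfan replicate 2, 476 without control replicate 1 and 468 without control replicate 2. Of the control calls 106 of the higher (56.8 expected if independent) and 53 of the lower genes (6.11 expected) were called in Marfan mice too. Many control calls did not share their direction: 1914 of 3952 higher and 178 of 440 lower ones lay on the same side in Marfan mice, and over all genes the changes correlated at a Spearman value of 0.0109 and a Pearson value of 0.232. These control calls include the shift of all genes (median 0.22). Of the Marfan calls 99 of 108 higher and 98 of 104 lower ones lay on the same side in control matched cells. There 44 (1.85 expected if independent) and 40 (3.99 expected) were called too, while the Spearman value over all genes was 0.0931.

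The share of modulation genes per smooth muscle cell was compared after cells were thinned to 6600 evened counts. Cells with fewer counts were left out, so that 1747 of 2204 cells of the male and 3777 of 3797 of the female control nonSHF library were kept. Without thinning, in all cells, 4.36% and 3.87% of the cells of these libraries lay above a threshold of 1.25%. More Marfan cells than control cells lay above the threshold of 1.27% of counts, in both lineages and both sexes. In SHF the share of cells above it was 5.77% ± 1.54 in control and 9.96% ± 2.28 in Marfan mice, and in nonSHF 3.98% ± 0.842 and 14.8% ± 5.59. The median share of modulation genes was 0.538% ± 0.0321 and 0.599% ± 0.0536 in SHF, and 0.614% ± 0.0107 and 0.689% ± 0.0750 in nonSHF, differences of about the spread between replicates. The median share of contractile genes was 6.73% ± 0.386 and 6.42% ± 0.284 in SHF, and 6.12% ± 1.33 and 6.67% ± 0.107 in nonSHF, each pair control and then Marfan, with differences smaller than the larger spread. These values were not tested.

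**Figure D3:**
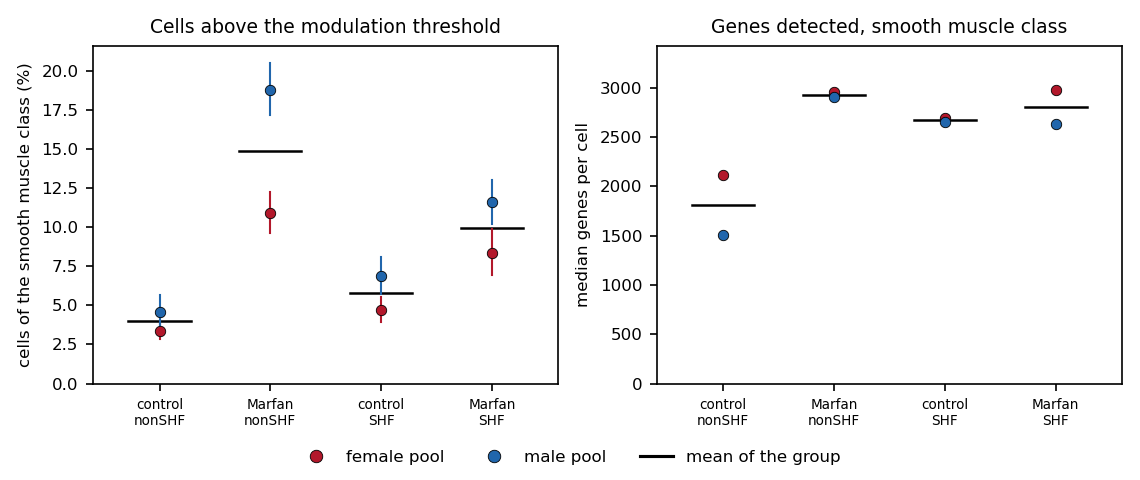
Left, percent of smooth muscle class cells per library whose share of modulation genes lies above the 95th percentile of control cells, with 95% exact binomial intervals. Right, median genes per cell of the same class. Marfan libraries lie above the control libraries of their lineage on the left, from 8.34% to 18.8% against 3.39% to 6.86%, and control nonSHF libraries lie lowest on the right.

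In untraced fibroblasts of Marfan mice 15 of 16 inflammation genes rose and 17 of 19 contractile genes fell. The mix of clusters in this class differed: one led by genes that include Ptx3, C3 and Igfbp6 held 157 and 45 control nonSHF cells (female and male) and 243 and 401 Marfan nonSHF cells, and the largest other one 258 and 86 against 368 and 254. Without the former Ptx3 (0.91, adjusted p = 0.0534), Comp (adjusted p = 0.0588) and Ccl2 (0.99, adjusted p = 0.0742) did not pass, and 2248 genes did. Apod, an apolipoprotein, rose by 2.02 ± 0.26 (relative 1.83 to a median of 0.19), the methyltransferase gene Inmt by 1.79 (1.59 under median-of-ratios scaling) and the chemokine Ccl7 by 1.71 (relative 1.52). Spp1 rose by 2.13 ± 0.62 (relative 1.94), with an adjusted p of 0.0679 under median-of-ratios scaling. The pentraxin Ptx3 rose by 1.65, cartilage oligomeric matrix protein (Comp) by 1.61 and Mmp3 by 1.45 (relative 1.46, 1.42 and 1.26), and the surface marker Thy1 rose by 1.41 relative to the median. Rgs5 changed by -1.43 (relative -1.62), Npnt, an integrin ligand, by -1.40 (relative -1.59), Pam by -1.38 (relative -1.57), S100a4 by -1.28 (relative -1.47) and the Wnt antagonist Sost by -1.27 (relative -1.46). Of 16 inflammation genes 15 rose (15 and 0 adjusted over the list alone), among them Cxcl12 by 1.10, Il1r1 by 0.79 and Ccl2 by 1.30 (camera adjusted p = 6.05e-05, and adjusted p = 0.533 with an estimated correlation). Ccl2 and Ccl7 are among the leading genes of the macrophage-like cells, which were more frequent in Marfan nonSHF libraries. Whether macrophage RNA accounts for such genes in fibroblasts was not tested. Of 12 interferon genes 6 rose (9 and 0), with Isg15 by 0.86 and Irf7 by 0.97. Of 19 contractile genes 17 fell (0 and 17), among them Cnn1 by 1.31, Myh11 by 1.18 and Tpm1 by 0.91 (camera adjusted p = 6.40e-16, and adjusted p = 0.533 with an estimated correlation). Contractile genes stood in fibroblasts at a median of 8.50% and 14.02% of their smooth muscle level in the female and male control nonSHF libraries and at 7.31% and 7.07% in Marfan nonSHF. Whether smooth muscle RNA in the fibroblast droplets accounts for their fall was not tested. Of 18 elastic fibre genes 5 rose and 5 fell (6 and 5 adjusted over the list alone), with Efemp2 (fibulin-4) changed by 1.28, and of 21 TGF-beta genes 4 rose and 4 fell (4 and 4), with Tgfbi changed by 1.08. Without Marfan nonSHF replicate 2 only Inmt, Thy1, Mmp3, Cxcl12, Efemp2 and Tgfbi of these named genes kept their calls, and without control nonSHF replicate 2 Spp1 stood at 1.47 (adjusted p = 0.134).

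In all 2538 of 7956 genes passed in untraced fibroblasts, 2045 higher and 493 lower, and with median-of-ratios scaling 646 higher and 880 lower. The count was 58 without Marfan nonSHF replicate 2, 783 without Marfan nonSHF replicate 1, 3933 without control nonSHF replicate 1, and 561 in matched cells. There Spp1, Comp, Isg15, Npnt, Cnn1, Sost and Myh11 (adjusted p from 0.0514 to 0.128) did not pass. Of these Spp1 stood at 2.69, Comp at 1.71, Npnt at -1.14, Cnn1 at -0.87 and Sost at -1.19 in matched cells, each in its direction in all cells. In SHF fibroblasts limma called 0 genes, with 311 at an unadjusted p under 0.05 and a smallest adjusted p of 0.211. The genes with the smallest p there were Hsd11b1 (1.13 ± 0.16), Ly6c1 (0.75), Epha3 (0.76), Thy1 (0.70) and Ahsg (0.68), none past the threshold. With only the libraries of the 2 groups 32 genes passed, and without both control nonSHF libraries 38, these 5 among them. On simulated data with a spread smoothed over genes the same fit recovered 82.1% of 1.5-fold and 98.5% of 2-fold changes, and with each gene's own spread 52.2% and 83.6%. These rates hold only for genes with a mean level above the median, in which the changes were set. The interaction also gave 0 genes by limma, with 1709 at an unadjusted p under 0.05, and Inmt at -1.24 (adjusted p = 0.114). It gave 3350 genes without control replicate 1, 925 without control replicate 2, 89 without Marfan replicate 1 and 14 without Marfan replicate 2.

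SHF and nonSHF fibroblasts, compared over both genotypes, differed in 4 genes. The chemokine Ccl4 was lower in SHF by -1.18 ± 0.10 (adjusted p = 0.0139). It is among the leading genes of the macrophage-like cells, which were nearly absent from the SHF libraries, and whether their RNA accounts for it was not tested. Also lower were the Wnt modulators Sfrp2 and Sfrp4, by -0.93 and -0.89 (adjusted p = 0.0489 for both). 1500015O10Rik (Ecrg4), which encodes the secreted peptide augurin, was higher by 1.44 ± 0.13 (adjusted p = 0.0143). Of 7956 genes 542 had an unadjusted p under 0.05. The count was 0 by limma without control replicate 1 (239 at an unadjusted p under 0.05) and 16 without control replicate 2. In matched cells it was 0 by limma (612), with Sfrp2 at -1.19 and Sfrp4 at -0.97 (adjusted p = 0.101 and 0.232). Sfrp2 had an adjusted p of 0.0692 under median-of-ratios scaling, and Sfrp2 and Sfrp4 lost their calls without Marfan replicate 1 (adjusted p = 0.0667 and 0.0822).

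Macrophages of Marfan mice, compared in the nonSHF fraction alone, held more transcripts of 5 of 13 inflammatory macrophage genes and 4 of 13 antigen presentation genes. This fit had 4 libraries and 1 residual degree of freedom, so its spread came mainly from the trend over all genes. On simulated data with a smoothed spread it recovered 70.1% of 1.5-fold and 100% of 2-fold changes, and 9.22% of its calls were false. With each gene's own spread it recovered 0% of 1.5-fold, 2-fold and 3-fold changes. With Leiden at 1.6 a dendritic-like cluster led by genes that include Ccl4, Cd74 and Il1b came apart, with 95 and 40 cells in control nonSHF and 272 and 146 in Marfan nonSHF, and the class fell from 305 and 293 to 210 and 253 control cells and from 725 and 618 to 461 and 472 Marfan cells. Il1b (1.11), Ccl3 (0.81) and H2-DMb1 (0.78) passed there too, and Cd163 (-0.39, adjusted p = 0.0626) did not. The median of all genes was 0.12, and relative to it each change is lower by that amount, as given for some genes. Gdf15, a stress cytokine, rose by 1.33 ± 0.12 (relative 1.22) from a level of 3.80 ± 0.102 to 9.78 ± 1.12, the mitochondrial nucleotide carrier gene Slc25a33 by 1.28 (relative 1.16), Areg, a ligand of the EGF receptor, by 1.19 (relative 1.07) and the actin regulator Coro1a by 1.18 (relative 1.06). Of 13 inflammatory macrophage genes 5 rose (8 and 0 adjusted over the list alone), among them Il1b by 1.11, Trem2 by 1.01 (relative 0.89) and Ccl3 by 0.87 (relative 0.75), with camera adjusted p = 0.000417 and adjusted p = 0.405 with an estimated correlation. Of 13 antigen presentation genes 4 rose (9 and 0), with H2-DMb1 by 0.84 and the immunoproteasome gene Psmb8 by 0.88. Of 12 resident macrophage genes 1 rose, Ccl8 by 0.78, and 2 fell, the scavenger receptor gene Cd163 by 0.54 and the factor Maf by 0.60 (1 and 3 adjusted over the list alone). S100a8 and S100a9, the calgranulins of neutrophils, passed the test with levels of 1.94 ± 1.11 and 3.51 ± 2.79 in Marfan mice. In control mice they stood near 0 counts, so that no fold is given. Cells with both made up 5 of 725 and 1 of 618 macrophage-like cells in Marfan mice. In control mice they were 0 of 305 and 0 of 293 (95% exact intervals reach up to 1.202% and 1.251%), and in smooth-muscle-like cells of the same 4 libraries 0 had both. Of 11 mitochondrially encoded genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), with mt-Atp6 higher by 0.88 relative to the median. In fits with group only, Il1b, Ccl3, H2-DMb1, Psmb8 and mt-Atp6 lost their calls without Marfan nonSHF replicate 1 (Il1b at an adjusted p of 0.0526), Ccl3, Trem2, Ccl8 and Psmb8 without Marfan nonSHF replicate 2, and Coro1a, H2-DMb1 and Psmb8 without control nonSHF replicate 2. In matched cells Ccl8 stood at 0.18 and did not pass.

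The 365 genes that fell in macrophages included contractile and elastic fibre genes, and were not sorted by cell type as a whole. All 19 contractile genes fell (0 and 19 adjusted over the list alone), among them Cald1 by 1.81, Myh11 by 1.78 and Tagln by 1.53 (camera adjusted p = 9.65e-31, and adjusted p = 0.405 with an estimated correlation), as did all 8 elastic fibre genes (0 and 8), with Eln by 1.68. Pam changed by -2.11, Ogn by -2.08, Aebp1 by -2.04, Nedd4 by -1.91, Pcdh7 by -1.90, Fmo2 by -1.86 and Fn1 by -1.52. Contractile genes stood in macrophages at a median of 6.35% and 8.78% of their smooth muscle level in the control libraries, and at 2.26% and 2.03% in the Marfan libraries. In all 600 of 6909 genes passed, 235 higher and 365 lower, and with median-of-ratios scaling 121 higher and 437 lower. The count was 49 with no sex term and 1087 without cells holding S100a8 or S100a9. With group only it was 157 without Marfan nonSHF replicate 1, 175 without Marfan nonSHF replicate 2, 2983 without control nonSHF replicate 1 and 916 without control nonSHF replicate 2, and Cd163 and Maf lost their calls without either Marfan library and without control nonSHF replicate 2.

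Endothelial-like cells were few, from 10 to 132 per library, and the male control nonSHF library with 10 cells was left out. The 16 genes that passed between Marfan and control nonSHF cells therefore rest on 1 control library of 28 cells, which is assumed to vary like the other groups, with 12 higher and 4 lower, or 12 higher and 11 lower with median-of-ratios scaling. Among the 12 higher were Odc1, the enzyme of polyamine synthesis, by 3.24 ± 0.41, Plcb4, a phospholipase, by 3.07, the leukocyte adhesion receptor Icam1 by 3.03 and the interferon regulatory factor Irf1 by 2.73 (relative 3.06, 2.89, 2.85 and 2.55 to a median of 0.18). Crip1 changed by -1.12 (relative -1.30), a call lost without either Marfan library (adjusted p = 0.164 and 0.133), as was that of Irf1 without Marfan nonSHF replicate 1 (adjusted p = 0.0504). With no gene filter 0 genes passed by limma (2113 at an unadjusted p under 0.05), and with equal cells and totals 0 (866). In SHF endothelial cells limma called 0 of 9253 genes between genotypes, with 414 at an unadjusted p under 0.05. Cd74, the invariant chain of class II antigen presentation, stood at 2.51 ± 0.39 and Cnn1 at -1.89 ± 0.29 (adjusted p = 0.287 for both). That count was 75 without control SHF replicate 2, 24 without control SHF replicate 1 and 2 without Marfan SHF replicate 1. Between SHF and nonSHF endothelial cells limma called 0 genes, with 314 at an unadjusted p under 0.05, and Fst stood at 1.97 and Lrg1 at -1.54 (adjusted p = 0.987 for both). That count was 15 without Marfan replicate 2, 5 without control replicate 1 and 1 without Marfan replicate 1. On simulated data with a smoothed spread the SHF fit recovered 29.9% of 2-fold and 89.4% of 3-fold changes, and with each gene's own spread 0, so the lack of calls does not show that endothelial cells did not differ.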

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

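Of the tests below, those of genes per cell in untraced smooth muscle, of whole libraries, of Xist counts, of female RNA, of evening in macrophages, of fibroblast markers and of the SHF part alone were chosen only after the result was seen.

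A difference between the groups marks the interaction in smooth muscle: the Marfan effect differed between SHF and nonSHF in 2774 genes by the test of the difference itself (limma). On the log2 scale, SHF minus nonSHF, the effect on Cytl1 differed by -1.13, on Spp1 by -1.10, on Atf5 by -0.98 and on Tnfrsf11b by -0.85. The effect on Pam differed by 1.10, on Tmsb10 by 1.07, on Col1a1 by 0.90 and on Thbs1 by 0.59. The count was 10 in matched cells, 653 in as many random cells and 0 by limma without Marfan replicate 2 (1620 genes at an unadjusted p under 0.05). With 217 genes higher and 2557 lower in SHF, median-of-ratios scaling gave 468 and 124. Spp1 stood at 0.84 in random cells and was not measured in matched cells, and Atf5, Pam, Tmsb10 and Tnfrsf11b did not pass in matched cells (adjusted p = 0.247, 0.0718, 0.221 and 0.291). There Atf5 stood at -0.92, Pam at 1.07 and Tmsb10 at 0.86, each in its direction in all cells.

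The first pattern weighed is the number of genes that differed between Marfan and control nonSHF smooth muscle. Fewer genes per cell in the control libraries fit as a part cause of the calls: cells of 1500 to 2300 genes kept 3.92% of them, and as many random cells 66.3%. Calls not tested in matched cells count as not kept. Of 4933 calls tested there 3909 kept their sign. Matched cells are a part of all cells, which by itself favours the same sign. A lost call does not show that a change was absent, and a kept sign does not show its cause. A difference of whole libraries cannot be told apart from a Marfan effect shared by cell types: 61.2% of 3780 called genes lay on the same side of each class's median in smooth muscle, fibroblasts and macrophages (25% by chance), and both predict this. Counts added when depth was evened may have a part, as 58.4% of cells of the male control nonSHF library held exactly 1 Xist count against at most 5.50% in other male libraries. RNA of female cells is argued against as the source of these counts, since it would bring Tsix along: that library held 0.217 Tsix counts per 100 Xist counts, and the female libraries at least 2.70. A Marfan effect in nonSHF cells is the biological explanation. Matched cells called 219 genes the same way, among them Igfbp2, Cytl1 and Kcnj15. Kept signs cannot decide this for the other calls, for which a Marfan effect stays open. It stays open for the 219 genes too, since matched cells still held fewer genes in control (medians of 1931 and 1641.5 against 2032 and 2102.5).

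The second pattern is the lower contractile genes in Marfan nonSHF macrophages. RNA of smooth muscle cells in the macrophage droplets fits: in each library at least 81.0% of contractile genes had a macrophage to smooth muscle ratio within 2-fold of that library's median. Evening cannot be told apart, with medians of -1.34 in the female and -1.46 in the male pair. Doublets cannot be told either, since the tenth of control macrophages with most contractile counts held 71.1% of them in one library and 44.2% in the other. A change of contractile genes within macrophages was not tested apart from these.

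The third pattern is the rise of modulation genes in Marfan smooth muscle of both lineages. Fibroblast RNA is argued against, since the 7 fibroblast markers measured of 14 had a median change of -0.0732 in SHF and -0.87 in nonSHF. RNA of the unnamed clusters was not tested apart, and Thbs1 and Vcam1 are among the leading genes of the largest one. A larger modulated cluster is not the whole cause, since 7 of 8 modulation genes stayed called in SHF without it. Genes per cell fit in part, for the nonSHF side: in matched cells the median change of the modulation genes was 0.97 in SHF and 0.41 in nonSHF, against 0.89 in all nonSHF cells. That fall includes the shift of all genes, whose median was 0.29 in all and 0.02 in matched nonSHF cells. It was not tested without this shift, so it does not show that genes per cell bear on the modulation genes in particular. For the SHF part alone the change did not fall, with 0.97 in matched cells beside 0.81 in all cells. The genes were chosen as called higher in these same SHF cells, so this cannot exclude genes per cell as a cause. Of them Igfbp2 and Thbs1 passed in matched cells, and the female Marfan SHF library held 98 such cells. A Marfan effect on these genes in SHF smooth muscle stays open. Whether it lies within cells or in a shift between smooth-muscle-like clusters was not tested.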

How the results depend on the processing

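The planned tests with edgeR and DESeq2 and the planned RLE scaling were not run, because the values are not raw counts. The minimum of genes and maximum of mitochondrial counts removed no cell and gave no other value. With a library left out a group may hold 1 library, which is then assumed to vary like the other groups. Of 193 alternative counts of genes 112 stayed within 1.5 times the count reported. Of 2905 alternative values of named genes 2508 kept direction and side of the threshold, 335 kept only the direction and no longer passed, 33 newly passed and 29 changed sign. Of 64 values without a test 56 stayed within the spread. Causes were not tested except where fewer cells, genes or libraries are the alternative itself. Control nonSHF cells hold the fewest genes. The replicate block (the pool as a pair) was replaced by no replicate block as an alternative, and of the counts this moved only that of fibroblast lineage, to 11. It ended 2 calls of named genes, Serpinf1 and Egr3 between lineages in Marfan cells (adjusted p = 0.0624 and 0.229), and no other.

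For the counts of genes, ranges with 1 library or pool left out (leave-one-out) come first. In SHF smooth muscle between genotypes 87 became 0 to 27, and 6 with no gene filter, 6 with no sex term, 391 with only the libraries of the 2 groups, 146 with a pseudocount of 0.5, 9 in matched cells and 262 without both control nonSHF libraries. In nonSHF smooth muscle 5588 became 3911 to 5291, and 226 in matched cells. The interaction count of 2774 became 0 to 3509, 0 with no gene filter, 1817 with equal cells and totals, 592 with median-of-ratios scaling, 10 in matched and 653 in as many random cells. Lineage in control smooth muscle, 4392, became 857 to 4050, 1566 with no gene filter, 2477 with scaling, 408 in matched and 1879 in random cells. Lineage in Marfan smooth muscle, 232, became 50 to 476, 122 with no gene filter, 71 in matched and 149 in random cells.

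In SHF fibroblasts between genotypes 0 stayed at 0 to 0, and became 13 with equal cells and totals, 32 with only the 2 groups, 1 without the cluster led by Igfbp6 and 38 without both control nonSHF libraries. In nonSHF fibroblasts 2538 became 58 to 3933, 1291 with no gene filter, 919 with equal cells and totals, 720 with no sex term, 1267 with only the 2 groups, 1526 with scaling, 561 in matched and 1528 in random cells. The fibroblast interaction, 0, became 14 to 3350, and 35 with equal cells and totals. Fibroblast lineage, 4, became 0 to 16, 0 with no gene filter, 0 with Leiden at 1.6, 10 with equal cells and totals, 11 with no replicate block, 2 with a pseudocount of 0.02, 0 in matched and 1 in random cells, and 1 without the cluster led by Igfbp6. Endothelial lineage, 0, became 0 to 15. Endothelial genotype in SHF, 0, became 0 to 75, and 3 with only the 2 groups. Endothelial genotype in nonSHF, 16, became 15 to 15, 0 with no gene filter, 0 with equal cells and totals, 73 with no sex term and 361 with a pseudocount of 0.02. In macrophages, with group only, 600 became 157 and 175 without Marfan nonSHF replicate 1 and 2, and 2983 and 916 without control nonSHF replicate 1 and 2. It became 1107 with no gene filter, 333 with equal cells and totals, 49 with no sex term and 1087 without cells holding S100a8 or S100a9. Of 309 list tests 106 passed with camera at the preset correlation, 0 at an estimated one and 18 with fry.

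With Leiden at 1.6 the share of the smooth muscle class was 70.2% in control nonSHF and 44.4% in Marfan nonSHF. The fibroblast-like share was 20.5% in control SHF, 12.9% in Marfan nonSHF and 24.1% in Marfan SHF, and the macrophage-like share 9.86% in Marfan nonSHF and 0.0959% in Marfan SHF. The contractile share of Marfan nonSHF cells in smooth-muscle-like clusters only was 6.84%.

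Values that changed sign follow, and for these the cause was not tested. Leave-one-out ranges run from lowest to highest. In SHF smooth muscle Fbn1 stood at -0.0047 with equal cells and totals, -0.0298 in smooth-muscle-like clusters only and -0.0185 with scaling, and from -0.11 (without Marfan SHF replicate 2) to 0.14 with a library left out, being -0.07 without control SHF replicate 2. Acta2 stood at 0.01 without Marfan SHF replicate 1, and ranged from -0.14 to 0.0186 (without control SHF replicate 2). Klf4 ranged from -0.0946 (without Marfan SHF replicate 1) to 0.46. Tagln stood at -0.0221 with scaling, -0.12 in matched cells and -0.04 without control SHF replicate 1, and ranged from -0.0676 (without Marfan SHF replicate 2) to 0.11. In nonSHF smooth muscle Fbn1 stood at -0.00062 with Leiden at 1.6, -0.10 in smooth-muscle-like clusters only, -0.38 with scaling, -0.22 in matched and -0.0691 in random cells, -0.00069 without Marfan nonSHF replicate 1, and ranged from -0.0242 (without control nonSHF replicate 2) to 0.0336. Klf4 stood at -0.0914 with scaling and -0.02 without Marfan nonSHF replicate 1, and ranged from -0.27 (without control nonSHF replicate 1) to 0.88. With scaling Acta2 stood at -0.0857 and Tagln at -0.14. In the interaction Vcam1 stood at 0.28 in smooth-muscle-like clusters only and 0.15 with scaling, and ranged from -0.55 to 0.18 (without Marfan replicate 2), and Spp1 stood at 0.84 in random cells. Between lineages in Marfan smooth muscle Spp1 stood at 0.33 in random cells.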

Other observations

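The tests of other splits of the libraries were limited to splits that part as many pools, a limit chosen only after the result was seen.

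Lymphatic endothelial-like cells made up 1.71% ± 0.187 of Marfan nonSHF and 0.972% ± 0.0356 of Marfan SHF cells, against 0.3005% ± 0.0755 in control nonSHF and 0.459% ± 0.0319 in control SHF. Dendritic-like cells, which present antigen, made up 0.864% of control nonSHF and 1.54% ± 0.538 of Marfan nonSHF cells, and 0.0797% ± 0.0355 of control SHF and 0.137% ± 0.1135 of Marfan SHF cells. Schwann-like cells made up 0.175% ± 0.156 of control nonSHF and 0.748% ± 0.0684 of Marfan nonSHF cells, and none of control SHF and 0.0291% of Marfan SHF cells. The largest unnamed cluster, with 5906 cells, was led by genes that include Prg4 (lubricin), Thbs1, the cardiac transcription factor gene Tbx20 and the fibroblast marker Dpt. Its mean evened count of the fibroblast marker Dcn was 141.7, against 77.3 to 103.0 in the fibroblast-like clusters, and that of Myh11 was 0.263. The fibroblast shares and tests may therefore leave out fibroblasts. Unnamed clusters together held 11.7% ± 1.64 of control nonSHF, 15.9% ± 1.01 of Marfan nonSHF, 24.2% ± 1.92 of control SHF and 28.3% ± 2.73 of Marfan SHF cells. None of these shares was tested.

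Lineage is compared within pools, so the real split was set against splits that part as many pools. In fibroblasts these are 8 splits, too few for a share under 0.05, and 1 of them, the real one, reached the real 4 genes, while the highest other gave 0. The other 27 splits leave both fractions of some pools on the same side, and 2 of them gave 1252 genes. These set both control nonSHF libraries with both libraries of 1 Marfan pool. With the pool as a block, such a split compares only SHF with nonSHF cells within the control pools. The 4 genes over both genotypes therefore do not show that control fibroblasts differed little between lineages. That comparison carries the fewer genes per cell of the control nonSHF libraries. For endothelial cells the real count was 0, which all 8 splits that part as many pools must reach, so that this decides nothing. The highest other of the 8 gave 2 genes, and the 27 splits that part fewer pools gave up to 435.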
